A study of Mactra quadrangularis with 2 samples.

How the data were processed

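Poly(A) RNA from the digestive gland of the clam Mactra veneriformis (given as Mactra quadrangularis in the organism label) was sequenced on an Illumina HiSeq instrument, per the labels' protocols. Clams were kept for 3 days either in water with the solvent DMSO at 0.05% by volume or in water with BDE-47, a brominated flame retardant, at a nominal 5 µg/L in the same solvent. The series text describes 3 replicates of 30 clams in each group and pooling of the glands of 30 clams for RNA extraction. The tables hold 1 library per group, and how the replicates entered it is not given in the sources used here.

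The authors deposited raw fragment counts for 124752 unigenes, which are transcript contigs assembled de novo without a genome, per the file headers and unigene names. The totals in the file headers, 15.6 M fragments for the control and 15.9 M for BDE-47, equal the sums of the counts. The authors' deposited FPKM values (fragments per kilobase of unigene, scaled to the counted total) were recomputed from those counts to within rounding. The authors' deposited log2 ratio is that of BDE-47 over control FPKM, with an FPKM of 0 set to 0.001, as recomputed here. The authors also deposited a p-value and an FDR per unigene, from a test that is not given in the sources used here. CASAVA 1.5 is named per the submitters' processing notes. The assembler, aligner and counter are not given in the sources used here. A second table holds the 17625 unigenes that the authors called, all with an FDR of at most 0.001 and an absolute log2 ratio of at least 1, with protein descriptions from the Nr and Swiss-Prot databases. Of these, 4337 had a description, and the first listed Nr match was used. Protein names are therefore those of the nearest database entry, often in another phylum. Unigenes outside the authors' calls carried no description in the tables used.

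With 1 library per group no unigene was tested for a difference between conditions and no p-value was computed. Percentiles and shares of sets of unigenes, with their intervals, describe these 2 libraries only. A unigene counted as higher or lower when the absolute log2 ratio of FPKM plus 0.1 was at least 1, when it had at least 20 fragments summed over the 2 libraries, and when the exact 95% conditional binomial (Clopper-Pearson) interval of the ratio excluded 1. These intervals cover counting error only, since the fragments were amplified by PCR without molecular identifiers and the animals of a pool were not measured singly. Folds are ratios of fragments per library total. Where a library had 0 fragments, the fold was computed against a floor of 3 fragments in that library and is written as at least that value. The lower limit of its 95% counting interval lies below that value, for instance at 306 for the at least 377-fold of CL16330.Contig1. A count of 3 fragments on a unigene of the median length of 395 bases corresponds to 0.486 FPKM in the control and 0.476 in BDE-47.

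The rule was tested on simulated counts for the BDE-47 against control comparison, drawn for all unigenes with 200 of them changed. It recovered 50 of 50 unigenes simulated 4-fold higher, 50 of 50 simulated 0.25-fold, 49 of 50 simulated 2.5-fold and 48 of 50 simulated 0.4-fold. These shares were not split by fragment count. They do not give the recovery at 20 to 100 fragments, where 18736 of the 25513 real calls lie. The rule called 1201 of 124552 unchanged unigenes, of which only the 88846 past the floor of 20 fragments could be called. The interval held the true ratio for 96.2% of these 88846. The simulation holds counting noise only, so it does not show how many of the real calls come from differences between pools of animals.

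The rule, 26 gene lists matched on words in the descriptions, and the choice of named unigenes were fixed before the data were examined. Named are the 12 highest and 12 lowest log2 ratios among described unigenes that passed the rule, had at least 100 fragments and were called by the authors, with 1 per description. From each list, up to 2 higher and 2 lower unigenes by the same floor are also named. Names come from the Nr or the Swiss-Prot description, which differ for some unigenes. Other names were chosen after their values were seen and are said to be so. The lists include markers of muscle, testis, ovary, ciliated and blood cells, and of algal food. Words in the lists matched some names by chance in 10 lists, and counts without those matches stand beside the fixed ones. Percentiles of each list's median log2 ratio had been planned. They were not run, since the descriptions cover only called unigenes, and neither were their alternatives. In their place, and chosen after the data were seen, stands the percentile of the number of higher members among 10000 random lists of described called unigenes, of the same size and matched on expression in 10 bins. It describes these 2 libraries, not the conditions. A list with fewer than 5 members past the rule has none.

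Alternatives fixed in advance were pseudocounts of 1 and 0.01 FPKM, no floor and a floor of 100 fragments, TMM factors (edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0), a minimum length of 500 bases, a log2 threshold of 2 and the authors' own calls. Alternatives added after the data were seen were the sum of contigs of one cluster (unigene names of the form CL number and contig number mark contigs that the assembly grouped), the omission of chance matches, of unigenes that best match copepods or ciliates, and of shell matrix members, 6 further lists, and library totals without the 100 most abundant unigenes. Computations used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.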

Results

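The digestive gland transcriptome was compared between clams exposed to BDE-47 and solvent controls, with 1 library of pooled glands per group. The control library held 15.6 M fragments and the BDE-47 library 15.9 M. A fragment was counted on 119178 of 124752 unigenes in the control and on 121628 in BDE-47, with medians of 19 and 18 fragments per unigene. No difference below has a replicate check. Each compares these libraries, and the intervals cover counting error only.

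Among the described unigenes that the authors called and that passed the rule of size, 36.1% were higher in the BDE-47 library. Against that background, more of the cytochrome P450 (10 of 13) and digestive enzyme unigenes (37 of 52) were higher, and fewer of the heat shock protein and chaperone (16 of 71) and ciliary unigenes (4 of 28). Summed by cluster, 5 of 12 cytochrome P450, 30 of 55 digestive enzyme, 12 of 62 chaperone and 1 of 26 ciliary clusters were higher, and 3, 7, 34 and 13 lower, with the rest not past the rule. Chaperones had 4 higher and 17 lower with 1 unigene per description (percentile 6.12), and 4 and 12 (percentile 19.5) also without ciliate and copepod matches. Digestive enzymes had 24 higher and 15 lower without copepod, ciliate and shell matrix matches, a restriction chosen after the values were seen. The fragments of the whole digestive enzyme list summed to 23314 in the control and 21225 in BDE-47. Unigene56099, whose nearest Swiss-Prot entry is PIF, a protein of the shell's nacre, had 16 fragments in the control and 18847 in BDE-47, a 1153-fold ratio (95% counting interval 710 to 2018). A cytochrome P450 1A1-like unigene (CL14307.Contig1), named for an enzyme of foreign compound oxidation, was 6.80-fold higher (5.44 to 8.58). Its cluster of 3 contigs, summed, had a log2 ratio of 1.43. Multidrug resistance protein 1 (Unigene4274), an ATP-driven efflux pump, was 3.53-fold lower (3.21 to 3.88).

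Of the 89164 unigenes with at least 20 fragments, 11092 were higher and 14421 lower in BDE-47 by the rule of size. The median log2 ratio of these 89164 was -0.11, and the TMM factors differ by 0.12 in log2, and with them 12721 were higher and 12407 lower. The share past the rule was 33.3% at 20 to 100 fragments, 21.3% at 100 to 1000, 15.9% at 1000 to 10000 and 9.77% at 10000 or more, where 25 unigenes were higher and 9 lower. The authors' deposited table gave 7597 unigenes as up and 10028 as down, and 15669 of these 17625 also passed the rule of size. Among described unigenes past the rule, 1471 were higher and 2606 lower (36.1% higher), which is the background for the list counts that follow. Below, the cluster log2 ratio is that of all contigs of a cluster summed, given for named contigs where it lies outside the contig's own counting interval.

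Among the 12 highest described unigenes, an amelogenin-like unigene (CL7923.Contig1) had 2 fragments in the control and 5909 in BDE-47, a ratio of 2893 (801 to 23894). A proline-rich protein (CL717.Contig3) had 3 and 5925 fragments, a ratio of 1934 (661 to 9380). A tyrosinase-like protein (Unigene44351), of an enzyme family that oxidises phenols, was 444-fold higher (298 to 694), and a Sushi and von Willebrand domain protein that also resembles PIF (Unigene41963) was 482-fold higher (308 to 801). A unigene with a shematrin-like Swiss-Prot match (Unigene55453) was listed at 0 in the control and at 505 fragments in BDE-47, at least 165-fold higher. Its Nr name is secretory eggshell protein precursor, of Clonorchis sinensis. The others were a WAP domain protein (Unigene40530, ratio 1174, interval 324 to 9696), a NOTCH2-like, mucin-like protein (Unigene49441, ratio 614, interval 210 to 2980), a GTPase IMAP family member 7-like protein (CL20266.Contig1, ratio 668) and a unigene resembling type-2 histone deacetylase 1 (Unigene57541, ratio 2153, interval 386 to 85088). A caspase with the Nr name caspase 8 and the Swiss-Prot match caspase 3 (CL16330.Contig1), of a family of cell death proteases, was at least 377-fold higher, with 0 and 1156 fragments. A baculoviral IAP repeat protein 7-B (CL7824.Contig2) was at least 74.7-fold higher, with a cluster log2 ratio of 2.76.

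The 12 lowest included several unigenes with 0 fragments in BDE-47. Inhibitor of apoptosis-1 (Unigene70965), of a family that blocks caspases, had 601 fragments in the control and was at least 205-fold lower. A pol-like protein (CL313.Contig3) was at least 204-fold lower (cluster log2 ratio -3.13), an SH3 and PX domain protein (Unigene73446) at least 221-fold, and alkylglycerol monooxygenase (Unigene73756), which cleaves ether lipids, at least 40.8-fold. A DPY-6-like unigene (Unigene70270) was at least 34.0-fold lower. A trypsin-like serine protease contig (CL3006.Contig4) had 210 fragments in the control and 0 in BDE-47, yet the summed contigs of its cluster had a log2 ratio of 0.41. Short-chain collagen C4 (CL17702.Contig2) had a ratio of 211 (58.0 to 1747) towards the control and BTB/POZ protein 6 (CL5724.Contig1) one of 220 (39.0 to 8712), while their clusters were lower by log2 ratios of -1.33 and -1.93. Heat shock 70 kDa protein 12B (Unigene66625) was 40.0-fold lower, a dynein-like contig (CL4488.Contig3) 32.7-fold (cluster log2 ratio -1.38), a fibrinogen C domain protein (Unigene72321) 27.7-fold and neurofilament heavy polypeptide (Unigene27562) 28.1-fold.

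**Figure D1:**
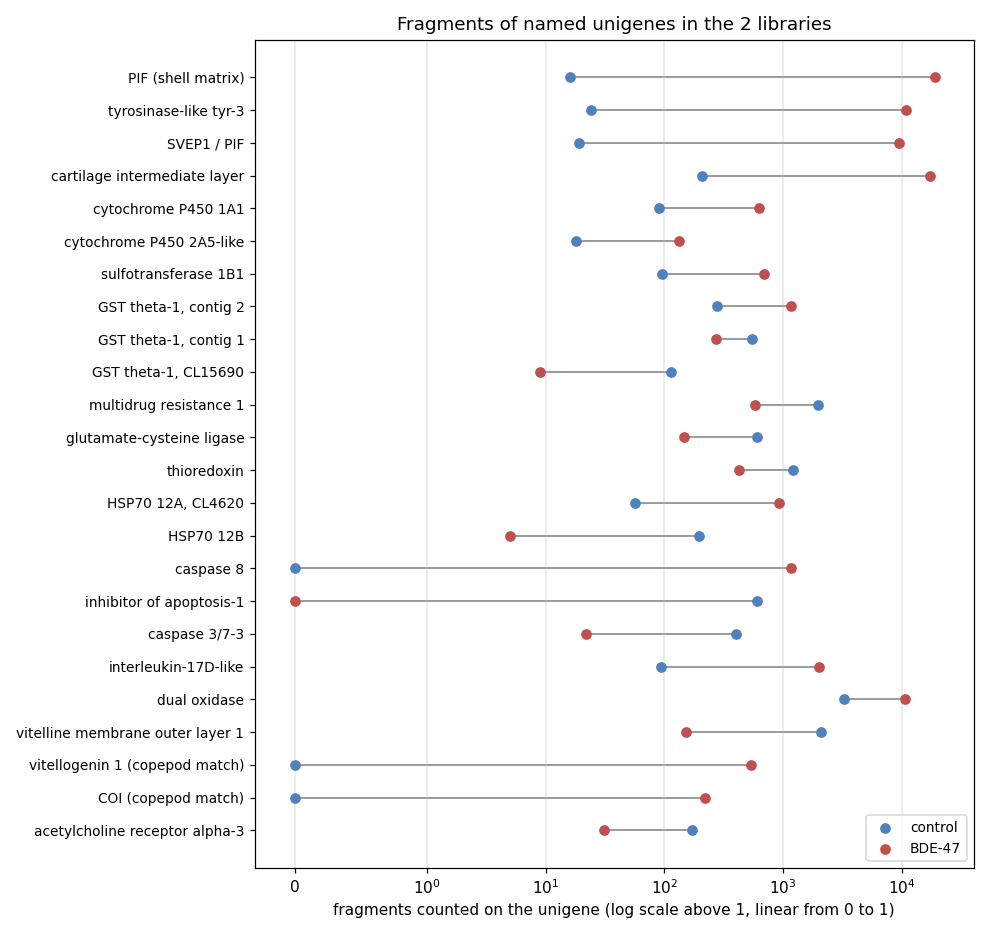
Fragments counted on 24 named unigenes (rows) in the control (blue) and BDE-47 (red) libraries, 1 library each, on an axis that is logarithmic above 1 fragment and linear from 0 to 1; grey lines join the 2 values of a unigene. The PIF-like unigene lies at 16 and 18847 fragments and inhibitor of apoptosis-1 at 601 and 0.

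Of the lists on foreign compound metabolism, only cytochrome P450 and other phase II enzymes had a percentile above 95 or below 5. Of 13 cytochrome P450 unigenes past the rule, 10 were higher and 3 lower, a number of higher members at the 99.8 percentile of random lists. With 1 unigene per description these counts held, and summed by cluster 5 were higher and 3 lower with 4 not past the rule. CL3645.Contig2, named cytochrome P-450, was 7.24-fold higher (4.41 to 12.6; cluster log2 ratio 1.42), whereas a P450 2F2-like unigene (Unigene36766) was 4.81-fold lower and P450 20A1 (Unigene36555) 2.56-fold lower. Of other phase I enzymes, 4 were higher and 3 lower, among them a zinc-binding alcohol dehydrogenase (Unigene41498, 2.79-fold higher) and fatty aldehyde dehydrogenase (CL19013.Contig2, 2.80-fold lower, cluster log2 ratio -0.39). Methylmalonate-semialdehyde dehydrogenase (CL9709.Contig1) was 2.06-fold lower (cluster log2 ratio -0.64). Of glutathione S-transferases, which conjugate glutathione to electrophiles, 5 were higher and 4 lower, and 1 and 2 after summing clusters. A theta-1 contig (CL14784.Contig2) was 4.17-fold higher while its sister CL14784.Contig1, chosen after its values were seen, was 2.03-fold lower, and the 2 summed had a log2 ratio of 0.79. Another theta-1 unigene (CL15690.Contig1) was 12.9-fold lower (6.58 to 29.0) and a rho class unigene (Unigene12240) 2.89-fold lower, while a sigma class unigene (CL10806.Contig2) was 2.33-fold higher (cluster log2 ratio 0.62).

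Of other phase II enzymes 14 were higher and 9 lower (percentile 99.1), and without sulfotransferases of glycans and lipids 7 and 2 (percentile 99.48). With 1 unigene per description the full list had 6 higher and 6 lower (percentile 83.2), and the shortened list 5 and 1 (percentile 98.495). Sulfotransferase 1B1 (Unigene1497), which adds sulfate to phenols, was 7.07-fold higher (5.70 to 8.86). Galactosylceramide sulfotransferase (CL2501.Contig18) was 2.34-fold lower as 1 of 42 contigs, with a cluster log2 ratio of -0.11. Heparan sulfate 3-O-sulfotransferase (Unigene44823) was 13.0-fold higher and carbohydrate sulfotransferase 1 (CL4533.Contig6) 2.72-fold lower (cluster log2 ratio -0.55). Of ABC and other efflux transporters 2 were higher and 9 lower (percentile 11.5), and summed by cluster 1 was higher and 5 lower with 5 not past the rule. Multidrug resistance-associated protein 5 (CL9585.Contig1) was 3.67-fold higher but not past the rule with its cluster summed (log2 ratio 0.60), and a second multidrug resistance protein (Unigene72958) was 3.40-fold lower. Antioxidant and metal binding unigenes went both ways, with 7 higher and 12 lower (percentile 44.9). The catalytic subunit of glutamate-cysteine ligase (Unigene889), the first step of glutathione synthesis, was 4.20-fold lower (3.50 to 5.06) and thioredoxin (CL1271.Contig1) 2.92-fold lower but not past the rule with its cluster summed (log2 ratio -0.56). A unigene that resembles extracellular superoxide dismutase, and whose Nr name is oocyte maturation arresting factor (CL3145.Contig2), was 32.6-fold higher, with a summed cluster log2 ratio of 0.41. Thioredoxin-like protein 1 (CL4291.Contig1) was 4.15-fold higher (cluster log2 ratio -0.06).

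Of 71 heat shock proteins and chaperones, 16 were higher and 55 lower (percentile 0.63), and 16 and 49 (percentile 2.17) without those that best match ciliates or copepods. Members of the HSP70 family 12, a subset chosen after the values were seen, made up 12 of the higher and 39 of the lower ones. HSP70 12A was 15.8-fold higher in CL4620.Contig1 and 18.6-fold lower in Unigene66628, and a 12B contig (CL2933.Contig5) was 12.3-fold higher (cluster log2 ratio 1.04). Of proteasome and ubiquitin unigenes 24 were higher and 67 lower (percentile 4.05), and 14 and 42 (percentile 5.03) with 1 per description. Summed by cluster, 12 were higher and 39 lower with 37 not past the rule. The ubiquitin ligase RNF213 (CL2670.Contig1) was 9.58-fold lower, with a summed cluster log2 ratio of -0.58, and a ubiquitin-60S ribosomal protein L40-like unigene (CL7301.Contig2) had 2 fragments in the control and 843 in BDE-47, a ratio of 413 (114 to 3414). A unigene with the Swiss-Prot match XIAP, a ubiquitin ligase (Unigene32312), had a ratio of 61.2 (16.6 to 511). CL17638.Contig2 was 5.15-fold lower (cluster log2 ratio -1.06). Its Nr name is 26S proteasome non-ATPase regulatory subunit 10 and its Swiss-Prot match is ankyrin-3.

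Apoptosis unigenes numbered 30 higher and 55 lower (percentile 29.4), and 24 and 49 (percentile 15.8) without chance matches. A contig with the Nr name caspase 3/7-3 and the Swiss-Prot match caspase 9 (CL14979.Contig2) was 21.1-fold lower (9.43 to 58.6). Of blood cell and immune unigenes 79 were higher and 97 lower. That number of higher members lay at the 99.0 percentile, and with 1 unigene per description (30 higher, 50 lower) at the 51.9 percentile. A sialic acid-binding lectin (CL20422.Contig2) was at least 67.9-fold higher (cluster log2 ratio 1.49) and ficolin-1 (CL11657.Contig1), a lectin of innate immunity, 21.4-fold lower (14.7 to 32.5). The serine protease inhibitor Cvsi-2 (Unigene54882) had a ratio of 39.2 (13.1 to 193).

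Digestive enzymes were the list fixed in advance with the highest percentile, 100. Of 52 unigenes, 37 were higher and 15 lower, and 27 and 13 (percentile 100) with 1 per description. The list's fragments, however, summed to 23314 in the control and 21225 in BDE-47. Endochitinase (Unigene44672) had 3 fragments in the control and 664 in BDE-47, a ratio of 217 (73.8 to 1054), and a trypsin (Unigene55748) was at least 64.6-fold higher, with its best Nr match in a copepod. Alpha-L-fucosidase (CL453.Contig2) was 3.21-fold lower, with a summed cluster log2 ratio of -0.09. Without unigenes that best match copepods or ciliates and without the chitinases that a shell matrix list chosen after the values were seen also holds, 24 were higher and 15 lower.

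Lipid metabolism had 20 higher and 22 lower unigenes, (percentile 93.2), and 20 and 18 with TMM scaling. Counting 1 per description, it had 18 higher and 15 lower (percentile 98.55), and summed by cluster 13 and 12 with 14 not past the rule. A heart-type fatty acid-binding protein (Unigene37031), a carrier of fatty acids, was 9.70-fold higher (6.18 to 16.0), and a low-density lipoprotein receptor-related protein (CL16739.Contig2) was 4.93-fold lower (4.64 to 5.25; cluster log2 ratio -1.64). Apolipoprotein D (CL6849.Contig1) was 4.87-fold higher (cluster log2 ratio 0.61) and another receptor-related protein (Unigene27097) 4.63-fold lower. Endocrine and nuclear receptor unigenes numbered 11 higher and 8 lower (percentile 97.1), 10 and 5 without chance matches, and 7 and 7 (percentile 85.3) with 1 unigene per description. Nuclear receptor 0B1 (CL14432.Contig1) was 3.25-fold higher (cluster log2 ratio 1.19) and ecdysone-induced protein 75B (Unigene36683) 2.30-fold lower. A unigene resembling ecdysone-induced protein 78C (CL5608.Contig5) was 3.18-fold higher (cluster log2 ratio 1.19) and asteroid homolog 1, held by chance (Unigene33039), 3.42-fold lower. Nervous system unigenes numbered 9 higher and 23 lower (percentile 18.6), and 6 and 22 (percentile 4.95) without chance matches or 5 and 15 (percentile 12.9) with 1 of those per description. Among them were an enterin neuropeptide (CL19373.Contig2, 17.1-fold lower, cluster log2 ratio -2.75) and an alpha-3 acetylcholine receptor subunit (CL1774.Contig1, 5.67-fold lower, summed cluster log2 ratio -0.16). Synaptosomal-associated protein 47 (CL12021.Contig2) was 3.82-fold higher (cluster log2 ratio 1.22), and so was, by 3.73-fold, a synaptonemal complex-like unigene that the list holds by chance (CL1477.Contig4, cluster log2 ratio -0.17). Solute carriers numbered 23 higher and 27 lower, and 24 and 21 with TMM scaling. The sodium-dependent phosphate transporter 2B (Unigene56000) was 32.6-fold higher and solute carrier 12 member 2 (CL16902.Contig1) 25.5-fold. Solute carrier 15 member 4 (CL1734.Contig4) was 5.11-fold lower (cluster log2 ratio -1.09) and solute carrier 12 member 4 (Unigene4731) 4.65-fold.

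Several lists held unigenes whose best Nr match was in another kind of organism. Mitochondrial respiratory chain unigenes numbered 10 higher and 7 lower (percentile 94.7), but 5 and 7 (percentile 53.0) without copepod matches. With 1 unigene per description they numbered 10 and 4 (percentile 99.3), or 5 and 4 (percentile 82.0) without copepod matches. Cytochrome c oxidase subunit I (Unigene58311), at least 71.8-fold higher, best matched a parasitic copepod, while succinate dehydrogenase cytochrome subunit (CL19898.Contig1) was 4.20-fold higher and cytochrome c oxidase copper chaperone (CL19902.Contig2) 4.05-fold lower (cluster log2 ratio -1.28). A contig with the Nr name of an NADH dehydrogenase iron-sulfur protein and the Swiss-Prot match mucin-22 (CL15046.Contig3) was 2.62-fold lower. Ribosomal proteins numbered 4 higher and 23 lower (percentile 2.52), 2 and 22 (percentile 0.335) without chance matches, and 4 and 12 (percentile 30.1) without ciliate and copepod matches. With 1 per description they numbered 3 and 20 (percentile 2.17), or 3 and 12 (percentile 17.9) without ciliate and copepod matches. Only 4 members had at least 100 fragments, 2 higher and 2 lower, or 0 and 2 without chance matches. The lower ones were mitochondrial proteins S25 (CL9192.Contig1, 3.03-fold, cluster log2 ratio -0.27) and L23 (CL7961.Contig1, 2.67-fold, cluster log2 ratio -0.81). Glycolysis and citrate cycle unigenes numbered 5 higher and 8 lower. Contigs 1 and 2 of phosphoglycerate mutase (CL19797.Contig1 and CL19797.Contig2) were 3.50-fold higher and 5.72-fold lower, with a cluster log2 ratio of -0.68. Phosphoenolpyruvate carboxykinase (Unigene41590), an enzyme of glucose synthesis, had a ratio of 37.9 (12.6 to 186). Its best Nr match was in an arthropod, Tribolium castaneum. Fructose-bisphosphate aldolase (CL6736.Contig2) was 6.47-fold lower (cluster log2 ratio 0.04).

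Ovary and egg unigenes numbered 14 higher and 9 lower (percentile 99.1), 9 and 2 (percentile 99.9) without chance matches, and 7 and 9 (percentile 71.4) without those that best match copepods. With 1 unigene per description they numbered 6 and 5 (percentile 91.7). Vitellogenin 1 (Unigene54733), a yolk precursor, was at least 177-fold higher, and vitellogenin 2 (Unigene52417) at least 64.0-fold, both with a best match in copepods and 0 fragments in the control. Vitelline membrane outer layer protein 1 (CL3834.Contig1) was 13.9-fold lower (11.8 to 16.5; cluster log2 ratio -2.86) and ovarian cancer-associated gene 2 protein (CL1761.Contig3) 2.99-fold (cluster log2 ratio -0.90).

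Testis and sperm unigenes numbered 2 higher and 14 lower (percentile 2.06), as they did with 1 per description, but summed by cluster 1 was higher and 4 lower with 12 not past the rule. Testis-specific tubulin alpha (Unigene11231), which holds most of the list's fragments, was 2.13-fold higher (2.06 to 2.20), and the list's fragments summed to 7212 in the control and 11892 in BDE-47. A testicular haploid expressed gene protein (CL6781.Contig1) was 3.16-fold lower (cluster log2 ratio -0.96). Cilia and axoneme unigenes numbered 4 and 24 (percentile 0.67), 2 and 20 (percentile 0.35) without chance matches, and 3 and 19 (percentile 1.52) with 1 per description, while summed by cluster 1 was higher and 13 lower with 12 not past the rule. Axonemal dynein heavy chain 5 (CL2753.Contig3), a motor of cilia, was 3.77-fold lower, with a summed cluster log2 ratio of -0.19, and sperm-associated antigen 6 (CL1550.Contig8) was 3.01-fold lower, with one of -0.97. A flagelliform silk-like unigene that the list holds by chance (Unigene54343) was at least 44.4-fold higher, and intraflagellar transport protein 52 (CL7315.Contig1) 2.34-fold higher (cluster log2 ratio -0.26). Muscle unigenes numbered 14 higher and 17 lower, and 12 and 14 without chance matches, among them a mantle muscle myosin light chain (Unigene56538, 8.04-fold higher) and a myosin heavy chain (Unigene69318, 5.67-fold lower). A contig with the Swiss-Prot match myosin light chain kinase (CL717.Contig7), in the cluster of the proline-rich protein above, had a ratio of 564 (101 to 22316). Its Nr name is a putative cell surface-expressed gene family of Trypanosoma congolense. A titin-like unigene (Unigene9525) was 4.89-fold lower. The algal food list had 1 lower member, chlorophyllide a oxygenase by its Nr name and a cholesterol desaturase by its Swiss-Prot match (CL18190.Contig3, 2.79-fold, cluster log2 ratio -0.29), and no higher one.

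DNA replication, repair and cell cycle unigenes numbered 32 higher and 75 lower (percentile 10.2), and 4 and 21 (percentile 1.43) without the RNA-directed polymerases of mobile elements. With 1 unigene per description the full list had 7 higher and 36 lower (percentile 0.23). All 4 of its unigenes named here are RNA-directed DNA polymerases of mobile elements, with Unigene40904 at least 89.1-fold higher, CL11448.Contig2 6.24-fold higher (cluster log2 ratio 0.62), CL11428.Contig1 22.8-fold lower and CL2591.Contig1 15.4-fold lower (cluster log2 ratio -3.49). Transposon and virus unigenes numbered 77 higher and 164 lower (percentile 9.03), and 65 and 151 (percentile 4.21) without chance matches or 28 and 65 (percentile 8.16) with 1 per description. A pol polyprotein (Unigene73310) was 28.6-fold lower (14.3 to 67.0) and a viral A-type inclusion protein (CL3147.Contig4) 35.0-fold (cluster log2 ratio -1.93). Extracellular matrix and adhesion unigenes numbered 42 higher and 57 lower (percentile 86.3). A matrix metalloproteinase 19-like unigene (Unigene56300), of a family that cleaves matrix, was 67.7-fold higher (47.0 to 101), and tenascin-X (CL2193.Contig1) 71.0-fold higher, with a cluster log2 ratio of 2.86.

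**Figure D2:**
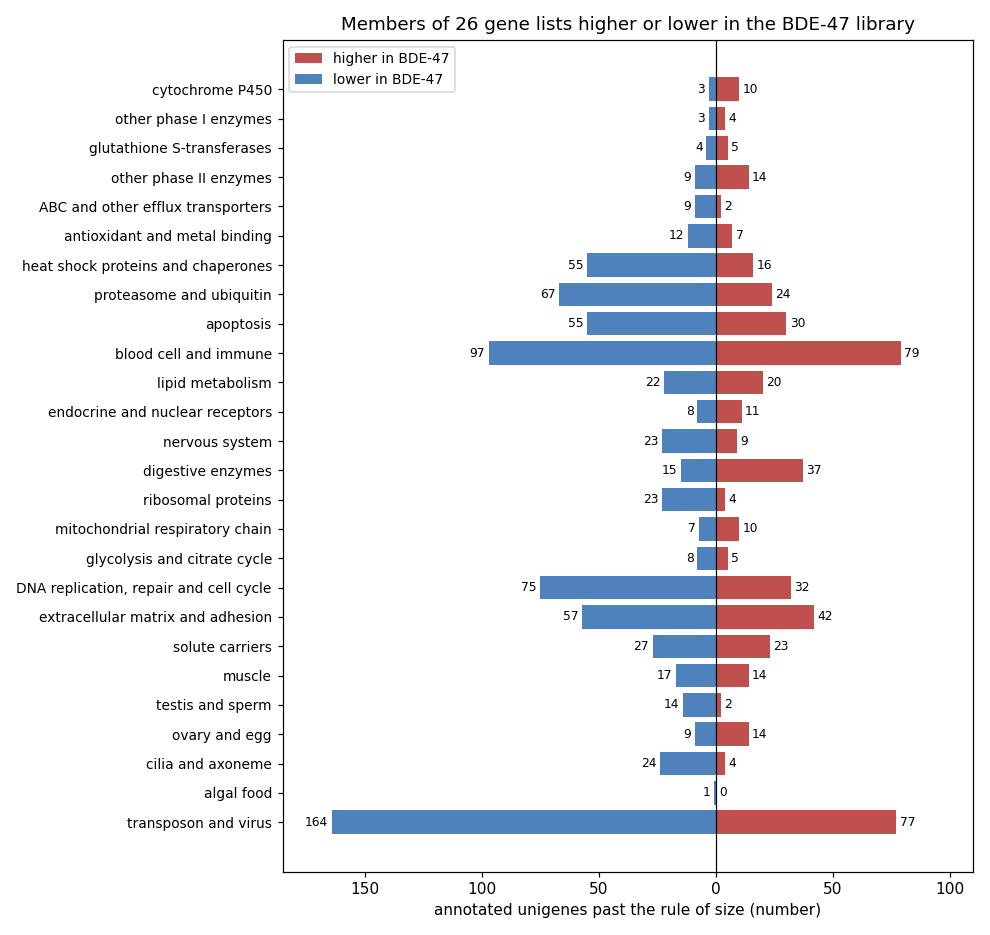
Numbers of annotated unigenes past the rule of size in each of the 26 gene lists (rows), with bars from 0 to the right for those higher in the BDE-47 library (red) and to the left for those lower (blue). Digestive enzymes had 37 higher and 15 lower, and heat shock proteins and chaperones 16 and 55.

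The calls count contigs, not genes. Summing the contigs of each cluster left 7136 higher and 9059 lower genes, and 76.3% of the 11556 called unigenes in clusters belonged to a cluster that was not called the same way. Of the 109 unigenes named under the fixed rules, 60 have a sister contig, and the summed clusters of 28 of these did not pass the rule. Among the other lists with a percentile above 95 or below 5, summed clusters left 9 higher and 3 lower with 7 not past the rule for other phase II enzymes, and 54, 52 and 55 for blood cell and immune unigenes. Endocrine and nuclear receptors had 7 higher and 5 lower with 4 not past, ribosomal proteins 2 and 21 with 6, and ovary and egg unigenes 11 and 5 with 7. Some lists passed these limits only without chance matches or with 1 unigene per description. Of these, DNA replication, repair and cell cycle had 17 higher and 59 lower clusters with 30 not past. Transposon and virus had 49 and 125 with 53, nervous system 6 and 15 with 14, and respiratory chain 7 and 2 with 7.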

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

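The sums by cluster, the totals without abundant unigenes, and the lists without copepod, ciliate, chance or shell matrix matches were chosen after the data were seen. Lower unigenes outnumbered higher ones under each pseudocount, floor, length and log2 threshold tried and in the authors' deposited calls, but not with TMM (12721 higher, 12407 lower) or median of ratios (12670 and 12442). Without the 100 most abundant unigenes in the totals, 11857 were higher and 13581 lower. The higher count moved by over 1.5 times with no floor (17626; the lower count of 19238 did not), and both counts did with a floor of 100 fragments (2789 and 3988), unigenes of at least 500 bases (5164 and 6206), a log2 ratio of at least 2 (4381 and 5164) and summed clusters (7136 and 9059), each of which changes how many unigenes can pass. List medians and their alternatives, length-matched random lists included, were not run because descriptions cover called unigenes only. No paired analysis was possible because each group has 1 library. Of the 25513 calls, 18736 lie at 20 to 100 fragments.

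Summing clusters turned the log2 ratio of 6 of the 109 named unigenes, to 0.41 (CL3006.Contig4), -0.058 (CL4291.Contig1, thioredoxin-like), -0.17 (CL1477.Contig4, synaptonemal complex-like), -0.68 (CL19797.Contig1), 0.039 (CL6736.Contig2, aldolase) and -0.26 (CL7315.Contig1, intraflagellar transport 52). It took a further 43 outside their counting interval or further outside it, and 28 of the 60 with a sister contig were no longer past the rule. TMM, the larger pseudocount and the authors' ratio turned none, but took 7, 67 and 0 outside the interval or further outside it. CL313.Contig3 and Unigene73446, for instance, already lay outside it in the main setting because of the pseudocount of 0.1. The difference of higher minus lower members turned in these lists: with a floor of 100 fragments, other phase I enzymes (-2), glutathione S-transferases (-1), solute carriers (1) and ovary and egg (-1); with TMM, lipid metabolism (2), solute carriers (3) and NF-kappa-B and interleukin-17 signalling (2); with 1 unigene per description, lipid metabolism (3) and NF-kappa-B and interleukin-17 signalling (1); with summed clusters, glutathione S-transferases (-1), blood cell and immune (2), lipid metabolism (1) and glycolysis and citrate cycle (1); without copepod and ciliate matches, respiratory chain (-2) and ovary and egg (-2). Apart from those 2 lists, where the omission itself is the cause, the cause was not tested.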

Other observations

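All 6 lists and all tests in this part were chosen after the data were seen. In all, 12 tests were tried, of which 5 are weighed here and 7 were replaced or dropped after their results were known; their values are given too. The shell matrix list (tyrosinases, PIF, perlucin, chitinases, lustrin and similar names) had 30 higher and 4 lower unigenes, and its fragments summed to 5448 in the control and 78050 in BDE-47. Cartilage intermediate layer protein (CL7653.Contig3) was 81.5-fold higher, a second tyrosinase-like protein (CL1241.Contig1) 35.7-fold, perlucin (CL7368.Contig2) 24.2-fold and lustrin A (Unigene5537) 21.5-fold, while a perlucin-like isoform (CL12208.Contig3) was 13.5-fold lower, with a summed cluster log2 ratio of -1.95.

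Caspases had 3 higher and 12 lower unigenes, with a contig of the Nr name caspase 3/7-3 and the Swiss-Prot match caspase 2 (Unigene36776) 18.6-fold lower, and inhibitors of apoptosis had 15 higher and 18 lower. In NF-kappa-B and interleukin-17 signalling, 17 were higher and 20 lower, and 17 and 15 with TMM. Interleukin-17D-like (CL3997.Contig1), a cytokine, was 21.3-fold higher (17.3 to 26.5) and dual oxidase (CL13272.Contig3), a source of hydrogen peroxide, 3.22-fold higher (3.10 to 3.35) but not past the rule with its cluster summed (log2 ratio 0.83), whereas a toll-like receptor (CL13100.Contig2) was 2.59-fold lower. Contigs 1 and 2 of IkappaB (CL18295.Contig1 and CL18295.Contig2) were 2.37-fold higher and 4.39-fold lower, and 0.08 in log2 ratio when summed. HSP70 family 12 had 12 higher and 39 lower members, with HSP70 12B (CL19262.Contig2) 13.1-fold lower (summed cluster log2 ratio -2.75). By cluster, that family had 9 higher and 23 lower with 11 not past the rule, and with 1 unigene per description 0 and 4. Acetylcholine receptors had 4 higher and 17 lower. Of unigenes with at least 100 fragments, 75 were listed at 0 in the control and 48 at 0 in BDE-47.

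Sister contigs of a cluster often went in opposite directions. Among 724 clusters of 2 contigs that both passed the rule, 525 (72.5%) did so, against 49.1% on average and 53.7% at most in 100 random regroupings of contigs matched on abundance. That share, first used as a test, restates the pattern. Summed, the 525 pairs had a median absolute log2 ratio of 0.36, against 0.46 at least and 0.53 on average in the random regroupings, so the 2 changes offset each other more than chance pairs do, which is consistent with reads of one gene being divided differently between sister contigs; alleles that differ between the pools of clams may do the same and were not tested. An earlier test met its own criterion, with 89.95% of both-direction clusters within 2-fold after summing. It was replaced because random regrouping gave nearly the same, 85.6% on average and 88.5% at most.

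Whether such splits made the higher shell matrix unigenes could be tested on only 6 of the 30, as the other 24 have no sister contig in the table. Of the 6, 5 (83.3%) passed the rule the same way with their cluster summed, too few to decide. The first form of this test gave 96.7%, but it counted the 24, which pass by definition. Summed by cluster, the whole list had 28 higher and 1 lower with 4 not past the rule, a count that also holds unigenes without a sister contig. Mantle tissue in the BDE-47 pool is a candidate source: of 29 called shell matrix unigenes with at least 100 fragments, 86.2% were higher, but the list was drawn up after its members were seen among the highest unigenes and holds only called ones, so this share decides nothing. Mantle RNA and a response of the gland to BDE-47 therefore cannot be told apart, and 9 members are chitinases or similar that the digestive enzyme list also holds.

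Some unigenes best matched copepods or ciliates. Of 13 past the rule that best matched the first set of copepod genera, 11 (84.6%) were higher, 10 of them at 0 in the control; this set was drawn from values already seen and is not a test. In 2 further copepod genera, all 7 called unigenes, 5 of them past the rule, were at 0 in the control, among them mitochondrial genes and elongation factor 1 alpha; 1 of the 7 had been seen before. Among 92 higher unigenes that best matched those 2 genera or other arthropods, 18.5% (95% exact binomial interval 11.1 to 27.9) were at 0 in the control. The share was 4.93% of 771 that best matched molluscs and 7.40% of all 1460 described higher unigenes outside the first set. The 1460 include the 92 and the 771. Without the 2 genera the arthropod share was 13.8% of 87 (7.34 to 22.9), an interval above the mollusc share that still held the 7.40%. The other arthropod matches therefore do not decide whether copepod RNA lay in the BDE-47 pool. Such RNA may account for the vitellogenins in place of a response of the clam. All 17 called ciliate matches with ribosomal or histone in a name were lower (100%, and 80.6% of all 62 ciliate matches). They include a nonhistone chromosomal protein (Unigene32138) and a receptor of activated protein kinase C (Unigene27883). Of 31 with such words that best matched animals, 64.5% (45.4 to 80.8) were lower, near the 63.9% of all described unigenes past the rule. Such words can hold other proteins too. The ribosomal protein list without ciliate and copepod matches had 4 higher and 12 lower (percentile 30.1). The 64.5% therefore does not decide whether ribosomal protein and histone transcripts were lowered in general. Called ciliate matches held fragments in both libraries, 5919 in the control and 3775 in BDE-47. More ciliate RNA in the control pool stays open. The ciliate set was drawn from values already seen, and 12 of its 62 were higher.

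A further 2 tests of the excess of lower unigenes were dropped from the weighing. With TMM the ratio of lower to higher was 0.975, against 1.30 in the main count, but TMM centres the ratios and fixes that outcome. Without the 100 most abundant unigenes in the totals it was 1.15, just above the bound of 1.1 set for abundant transcripts as the source, and the log2 shift of 0.05 covers part of the 0.12 between the TMM factors.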
